A study of Homo sapiens with 8 samples.

How the data were processed

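RNA bound by 2 RNA-binding proteins was measured by enhanced crosslinking and immunoprecipitation with sequencing (eCLIP) in A172 cells, an established human glioma line. PTBP1 is the polypyrimidine tract-binding protein 1, a regulator of splicing, and IGF2BP2 is an insulin-like growth factor 2 mRNA-binding protein, also called IMP2, which binds mature mRNAs. Per the labels, cells took up 500 µM 4-thiouridine for 3 h and were crosslinked with 2 exposures of 400 mJ/cm2 at 365 nm. RNA was cut with RNase I, 2% of each sample was kept as its input before the immunoprecipitation (IP), and membrane pieces of about 55 to 130 kDa (PTBP1) or 65 to 140 kDa (IGF2BP2) were taken. Libraries of 175 to 350 bp were cut from a gel. The 8 samples fall into 4 groups of 2, an IP and an input group for each protein. Peak lists of the 4 IP libraries were used, and the 4 input libraries as such are not analysed here. The labels say that each experiment was done 2 times. Nothing says whether these came from separate cultures, so p-values measure the spread between these libraries only.

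The submitters' processing notes name HISAT2 and the hg38 build, with no version. The peak caller, the gene annotation and the filters are not given in the sources used here. Each list was deposited per IP library, not pooled. Per the file headers, each line gives a chromosome, start, end, strand, gene, transcript region and the nucleotides that overlap the annotated feature, deposited as an overlap length. The authors also deposited a −log10 p per peak, which runs from 0 to 400 and stops there. A further deposited column is headed as a count but holds log2 values. They equal the log2 ratio of whole IP reads to whole input reads plus a constant for each chromosome. The commonest value on each chromosome is that of 3 IP reads to 1 input read. With that constant, a two-sided exact binomial test of 3 against 1 reads gave the deposited −log10 p on 24 of 24 chromosomes in every library. That the divisor is the input is read from the values, as no source used here states it.

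From both columns the IP and input reads were recovered for peaks with a log2 of at least 0 and a −log10 p above 0 and below 400, with a tolerance of 1% on the −log10 p, which had to match that exact test or a chi-square test with continuity correction. This worked for 98.7% and 98.4% of such peaks of PTBP1 replicates 1 and 2, and for 99.5% and 99.6% of those of IGF2BP2. On simulated peaks 99.1% of the reads came back right. The recovered reads were used to place all chromosomes of a library on one common scale, the median of its chromosome constants, and to recompute the p. A peak is called enriched below when its log2 on this common scale and its recomputed −log10 p are both at least 3. Peaks whose reads were not recovered kept the deposited −log10 p. This common scale was chosen after seeing the data. Peak scores are ranked only within a list, but numbers of enriched peaks and regions are also set side by side for both proteins. The bar differs between them. The constant of the common scale was -0.30 and -0.08 in PTBP1 replicates 1 and 2, and 1.74 and 1.90 in those of IGF2BP2. An IGF2BP2 peak thus needed fewer IP reads per input read to reach a log2 of 3.

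Repeated lines (at most 55 per list) were removed. A peak counted as shared when a peak of the other list overlapped it by at least 1 nt on the same strand. A reproducible region joins overlapping peaks of both replicates of a protein. Abutting peaks without overlap were not joined, so 1 broad site can count as several regions. Of neighbouring peaks in a list, 8.1% and 8.3% abutted in PTBP1 replicates 1 and 2, and 22.1% and 22.5% in those of IGF2BP2. As a background, each peak was moved 100 times to a random place in its gene, with gene extents of the RefSeq table for GRCh38.p14. Of 19767 gene names in the files, 19000 (96.1%) matched that table, and 92.2% to 92.5% of the peaks of a list could be moved. A second background moved regions by 500 nt. Shares of single lists carry 95% Wilson intervals, which cover counting error only. Overlap code was checked against a brute-force search on simulated intervals, with 100% the same.

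Shares of peaks per transcript region, as the files annotate them, were compared between the proteins with a two-sided exact permutation test, whose smallest possible p with 2 libraries against 2 is 0.333. Peak density per gene was log2((peaks + 0.5)/(peaks in the list + 1) × 10000) for genes with at least 10 peaks over the 4 libraries. It was tested with limma 3.58.1 (trend, R 4.3.3), PTBP1 minus IGF2BP2, with Benjamini-Hochberg adjustment at 0.05. A fold of this measure is a fold of the gene's share of its list, with the pseudocount added. PTBP1 lists held more peaks, so equal peak numbers in all lists give a negative difference, toward IGF2BP2. The pseudocount pulls genes with few peaks toward that value, not toward 0. With a pseudocount of 2 in place of 0.5, the median difference over genes moved from -0.01 to -0.10. The fit was also run on peak numbers simulated for the comparison of both proteins over 14684 genes. It recovered 38% of 100 genes changed 2-fold and 87% of 100 genes changed 4-fold, and 2.34% of its calls were false. The simulated replicates varied little beyond counting error (dispersion 1e-04), and few genes were changed. The 2.34% is thus not an error rate of the calls reported below. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, over 11 lists. Shared target genes were set against independent lists (n1 × n2/N), with no p because genes are not matched on abundance.

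The genes named follow a rule fixed, with the lists, tests and first alternatives, before the data were examined. It takes per direction the 10 largest density differences among genes past the threshold that separate both replicates of one protein from both of the other and hold at least 10 reproducible regions of the higher protein. It also takes per protein the 10 genes with the most reproducible regions, the 10 reproducible regions with the best deposited score (the lower of both replicates), and examples of each list with the most reproducible regions. Since many regions reached the limit of 400, ties were broken by the lower log2 of both replicates. Some genes that the rule takes are not given here. The genes with the most enriched regions in coding sequence and in 3′ UTRs were chosen after their values were seen.

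The first alternatives were another overlap rule, the best 25% of each list by score, reproducible peaks only, nucleotides covered, no filter, TMM scaling, a pseudocount of 2, exonic peaks only, a replicate block and leaving out each replicate. Added after seeing the data were enriched peaks, peaks of at least 10 IP reads, peaks over 4 nt, abutting peaks counted once, no peaks mirrored on the other strand, no chromosomes 14 and 21, and single exonic regions. Motif counts, distances of intronic peaks to exons and positions inside 3′ UTRs need a genome sequence or exon annotation, which are not used here. Computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.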

Results

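The series asked which RNAs are bound by PTBP1 and by IGF2BP2 in A172 glioma cells. Peaks of 2 IP libraries per protein were compared. The PTBP1 lists held 600615 and 538802 peaks with a median length of 40 and 38 nt, covering 27.2 and 23.4 Mb. The IGF2BP2 lists held 362700 and 341305 peaks with a median length of 21 and 20 nt, covering 8.67 and 8.0 Mb. The median recovered depth was 12 and 9 IP reads per peak for PTBP1 and 4 in both IGF2BP2 libraries. Peaks of exactly 3 IP reads, the fewest found, made up 11.0% and 14.3% of the PTBP1 peaks with recovered reads and 32.3% and 33.0% of the IGF2BP2 peaks. Among peaks with recovered reads, a typical IGF2BP2 peak therefore rested on fewer reads than a PTBP1 peak. Depth over whole lists is not known. Peaks with a −log10 p of 0, whose reads were not recovered, made up 25.2% and 22.3% of the PTBP1 lists and 11.5% and 10.8% of the IGF2BP2 lists.

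Enriched PTBP1 peaks lay in coding sequence and enriched IGF2BP2 peaks in 3′ UTRs far more often than those of the other protein. The bar was unequal, as an IGF2BP2 peak needed fewer IP reads per input read to count as enriched. Coding sequence held 26.8% ± 0.28 (SD, n = 2) of the enriched PTBP1 peaks and 5.54% ± 0.27 (SD, n = 2) of the enriched IGF2BP2 peaks. The 3′ UTRs held 2.45% ± 0.08 (SD, n = 2) of the enriched PTBP1 peaks and 15.1% ± 0.11 (SD, n = 2) of the enriched IGF2BP2 peaks. Peaks of at least 10 IP reads, enriched or not, differed less in coding sequence, a choice made after seeing the data. Coding sequence held 22.7% ± 0.82 (SD, n = 2) of these for PTBP1 and 12.3% ± 0.15 (SD, n = 2) for IGF2BP2. The 3′ UTRs held 3.63% ± 0.08 (SD, n = 2) and 14.7% ± 0.25 (SD, n = 2). MACF1 and DST, giant linkers of actin filaments and microtubules, held 30 and 16 coding-sequence regions enriched in both PTBP1 replicates, against 0 and 1 of IGF2BP2. CHST3, a carbohydrate sulfotransferase, and FGFRL1, a receptor of the FGF receptor family, held 12 and 11 enriched 3′ UTR regions of IGF2BP2 and 0 of PTBP1. Introns held the largest share for both, 61.9% ± 0.13 (SD, n = 2) of the enriched peaks for PTBP1 and 70.3% ± 0.33 (SD, n = 2) for IGF2BP2.

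Over all peaks, enriched or not, the differences had the same direction and were smaller. Coding sequence held 13.4% ± 0.19 (SD, n = 2) of the PTBP1 peaks and 9.21% ± 0.05 (SD, n = 2) of the IGF2BP2 peaks, a difference of 4.18 percentage points. The 3′ UTRs held 3.21% ± 0.11 (SD, n = 2) and 6.70% ± 0.14 (SD, n = 2), a difference of -3.49 points. Intron shares were close, at 73.8% ± 0.33 (SD, n = 2) for PTBP1 and 74.5% ± 0.23 (SD, n = 2) for IGF2BP2, a difference of -0.68 points. The sign of this intron difference turned with the nucleotides covered (1.15 points), for peaks over 4 nt (0.13 points) and for peaks of at least 10 IP reads (2.36 points). All 3 differences exceeded the SD of either protein, and the two-sided exact permutation test gave p = 0.333 for each, the smallest that 2 libraries against 2 allow.

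**Figure D1:**
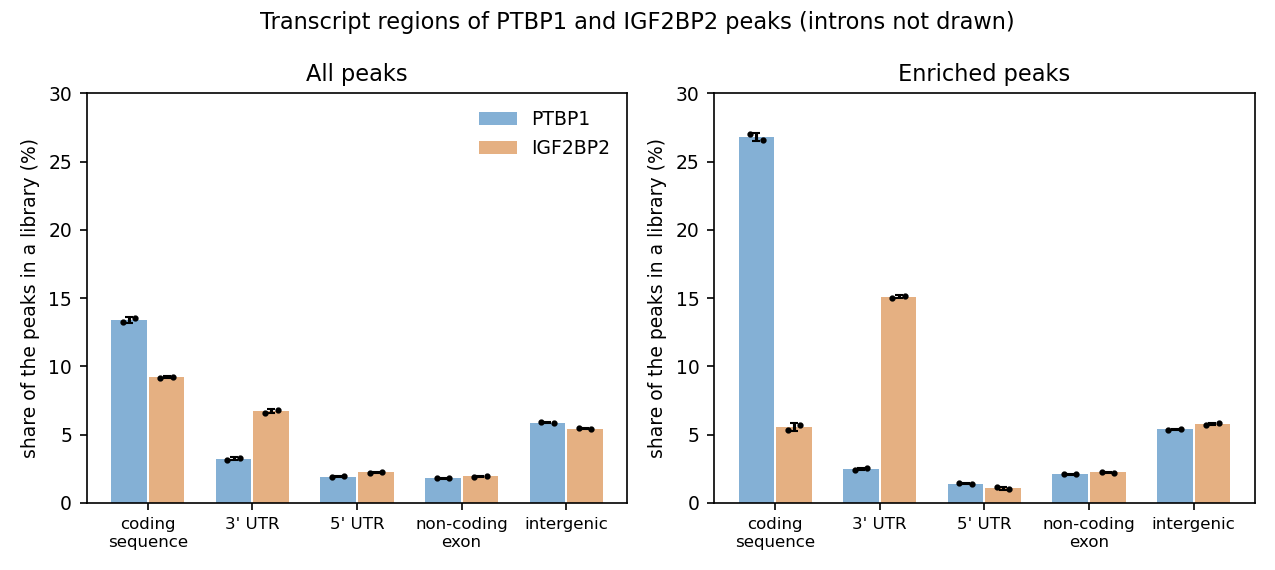
Share of the peaks of a library (percent, y axis) by annotated region (x axis), for all peaks and for enriched peaks. Bars are means of 2 libraries with SD and points are single libraries; coding sequence reached 26.8% of the enriched PTBP1 peaks and 3′ UTRs 15.1% of the enriched IGF2BP2 peaks.

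Scores of peaks were also compared within their own region and within their own gene. In IGF2BP2, 20.9% ± 0.03 (SD, n = 2) of the 3′ UTR peaks were enriched, against 8.75% ± 0.09 (SD, n = 2) of the intron peaks and 5.57% ± 0.31 (SD, n = 2) of the coding-sequence peaks. In PTBP1, 5.73% ± 0.27 (SD, n = 2) of the coding-sequence peaks were enriched, against 2.40% ± 0.04 (SD, n = 2) of the intron peaks and 2.18% ± 0.05 (SD, n = 2) of the 3′ UTR peaks. Among genes with at least 3 peaks in both regions, the median 3′ UTR peak of IGF2BP2 scored 1.29 and 1.26 log2 units above the coding-sequence peaks of its gene in the 2 replicates (1558 and 1440 genes). For PTBP1 the difference was -0.28 and -0.26 (1626 and 1537 genes), and it was 0 and -0.09 among peaks of 10 to 20 IP reads (1158 and 1156 genes with at least 1 peak in both regions). Coding sequence scored 0.21 and 0.12 above the introns of the gene in PTBP1 and -1.0 and -1.08 against them in IGF2BP2.

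After MACF1, the genes with the most enriched PTBP1 regions in coding sequence were EIF3C, a translation initiation factor subunit, with 24, then DST, PRRC2C with 15, MKI67, the proliferation marker Ki-67, with 14, CENPF, a kinetochore protein, with 13, and BAZ1B with 12. CEP170 and CLIP1, which encode proteins of microtubules, held 10 each. IGF2BP2 had 2 enriched coding-sequence regions in PRRC2C and 0 in EIF3C, MKI67, CENPF, BAZ1B, CEP170 and CLIP1. Regions of EIF3C spread over 335 kb of chromosome 16 (28390367 to 28725012), which holds a near-identical copy, so the placement of its reads is uncertain. For IGF2BP2 in 3′ UTRs, CHST3 and FGFRL1 were followed by ANKRD33B, CDC42EP3, the transcription factor genes FOSL2 and MEF2D and the fatty acid desaturase gene SCD with 10 each, and by the cyclin D1 gene CCND1, SOGA1 and STK35 with 9 each. PTBP1 had 4 enriched 3′ UTR regions in SCD, 2 each in FOSL2 and SOGA1 and 1 in MEF2D. The α-tubulin genes TUBA1C and TUBA1B, near-identical in sequence, held 11 and 9 enriched coding-sequence regions of IGF2BP2, and the mucin gene MUC5B 9. PTBP1 had 3 in TUBA1B and 0 in TUBA1C and MUC5B. Abutting regions were counted separately here, so these numbers need not be numbers of separate binding sites. The 11 regions of FGFRL1 lay within 0.7 kb and the 11 of TUBA1C within 0.75 kb. The genes in this paragraph were chosen after their values were seen.

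**Figure D2:**
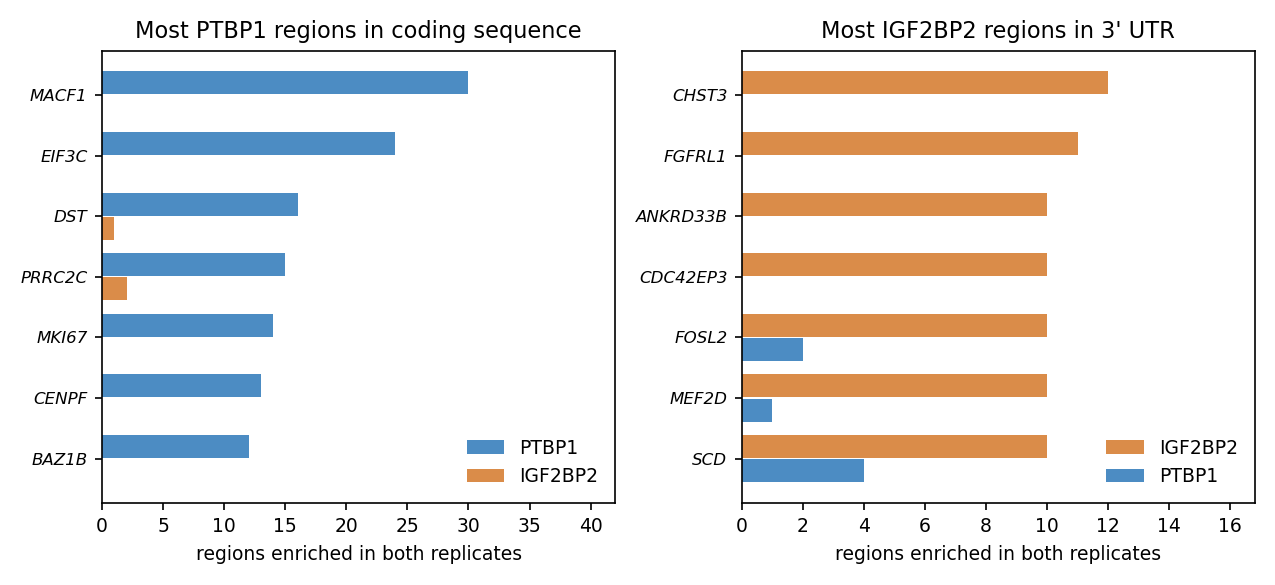
Number of regions enriched in both replicates (x axis) for the 7 genes with most PTBP1 regions in coding sequence and the 7 with most IGF2BP2 regions in 3′ UTRs, with both proteins as bars. MACF1 has 30 regions of PTBP1 and 0 of IGF2BP2, and CHST3 has 12 of IGF2BP2 and 0 of PTBP1. Abutting regions are counted separately.

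The strongest reproducible PTBP1 regions by the deposited score lay mostly on chromosomes 14 and 21. Both replicates reached the limit of 400 in 1148 PTBP1 regions and 544 IGF2BP2 regions. Of the 10 that led for PTBP1, the coding-sequence region of HSP90B1, a chaperone of the endoplasmic reticulum (chromosome 12, 103947311 to 103947413, plus strand, log2 8.09 and 7.41), was the only one elsewhere in the genome. The others lay in introns of the pseudogene DUXAP10 (2 regions), in coding sequence of the chaperone gene HSP90AA1 (chromosome 14, 102085758 to 102085840, log2 7.92 and 8.0), in an intron of ACTN1 (chromosome 14, 68878827 to 68878912, log2 7.31 and 7.85), in SNHG10 on both strands, in LOC100507412 (2 regions) and in the ribosomal RNA gene RNA28SN5. All coordinates are of hg38.

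For IGF2BP2, the 10 regions that led by the deposited score included 7 in 3′ UTRs, and 3 lay on chromosome 14. FGFRL1 had 3 of them close together in its 3′ UTR (chromosome 4, 1025764 to 1026260, plus strand), and the first scored a log2 of 7.68 and 8.14. HEG1, a membrane protein of endothelial junctions, had 1 in its 3′ UTR (chromosome 3, 124966123 to 124966190, minus strand, log2 7.34 and 7.43). IRF2BPL had 1 (chromosome 14, 77024770 to 77024825, log2 8.29 and 8.49) and ZFP36L1, which encodes an mRNA decay factor, had 2 (the first at 68788702 to 68788728 of chromosome 14, log2 7.82 and 8.07). The others lay in introns, at PLXND1 (chromosome 3, 129605287 to 129605314) and 2 in ZBTB46 on both strands (chromosome 20, from 63815336 to 63816079).

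The deposited scores were not on one scale across chromosomes. As deposited, 51% and 49.5% of the PTBP1 peaks on chromosomes 14 and 21 had a log2 and a −log10 p of at least 3, against 3.93% and 4.02% on all others. For IGF2BP2 these shares were 32.1% and 42.2% against 7.60% and 9.60%. On the common scale they were 2.55% and 2.45% against 2.92% and 2.83% for PTBP1, and 8.32% and 9.06% against 9.22% and 9.36% for IGF2BP2. Without chromosomes 14 and 21, the enriched PTBP1 regions at the limit of 400, 161 in all, included at the top those of HSP90B1, the cytosolic chaperone gene HSP90AB1 in coding sequence (chromosome 6, 44250303 to 44250420, log2 7.22 and 6.67), SNHG12 in an intron, ANP32B in coding sequence (chromosome 9, 98015364 to 98015426, log2 7.15 and 6.52) and the chromatin protein gene HMGB1, annotated to its 3′ UTR (chromosome 13, 2 regions from 30461360 to 30461500), besides 3 of the first 10 in no gene. That ranking was added after seeing the data. It still orders regions by the deposited log2, so differences in scale between the other chromosomes remain in it. On the common scale ANP32B (log2 7.15 and 6.54) lay above HSP90AB1 (6.37 and 5.81).

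**Figure D3:**
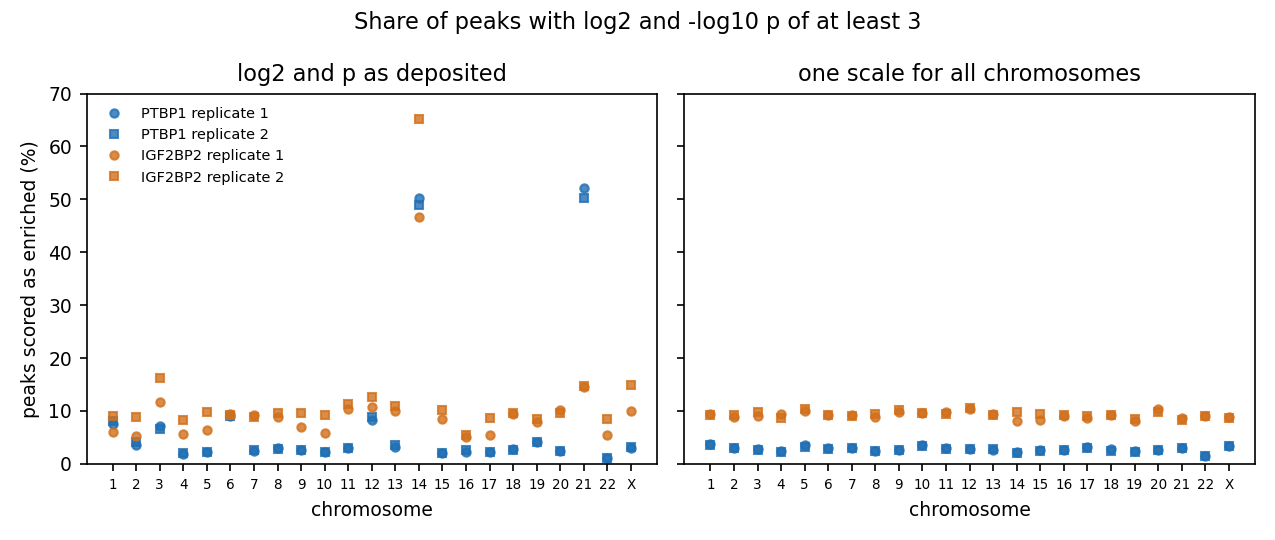
Peaks with a log2 and −log10 p of at least 3 (percent of the peaks of a chromosome, y axis) by chromosome (x axis), as deposited and on one scale for all chromosomes, with a point per library. PTBP1 replicate 1 falls from 50.3% to 2.21% on chromosome 14 and from 52.2% to 3.05% on chromosome 21.

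Most peaks of 3 of the 4 lists were found again in the other replicate. PTBP1 replicates 1 and 2 shared 55.6% (95% Wilson interval 55.5% to 55.7%) and 61.5% (61.4% to 61.6%) of their peaks, against 7.91% and 8.77% for peaks moved inside their genes. IGF2BP2 replicates shared 48.2% (48.1% to 48.4%) and 51.6% (51.4% to 51.8%), against 4.73% and 5.04%. PTBP1 replicates 1 and 2 overlapped 37.0% and 34.5% of the peaks of IGF2BP2 replicate 1. For IGF2BP2 replicate 2 these shares were 37.1% and 34.6%. An IGF2BP2 list overlapped 19.2% to 21.2% of the peaks of a PTBP1 list. The excess over moved peaks between replicates thus need not be specific to a protein. The share found again in the other replicate rose with depth in every library. In the order PTBP1 replicates 1 and 2, IGF2BP2 replicates 1 and 2, it was 12.3%, 19.3%, 27.1% and 31% at 3 IP reads. Above 50 reads it was 91.6%, 94.9%, 95.6% and 95.9%. Joined, PTBP1 had 303982 reproducible regions in 15661 genes and IGF2BP2 159702 in 13778 genes. Of these, 6990 regions in 2767 genes were enriched in both PTBP1 replicates and 9494 in 3836 genes in both IGF2BP2 replicates.

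**Figure D4:**
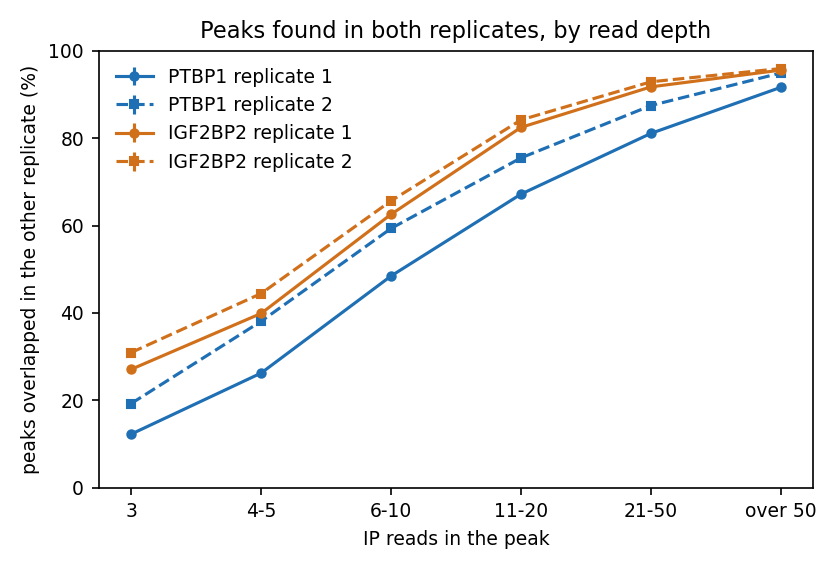
Share of the peaks of a library that a peak of the other replicate overlaps (percent, y axis) by recovered IP reads per peak (x axis), with 95% Wilson intervals smaller than most points. It runs from 12.3% to 31% at 3 reads and from 91.6% to 95.9% above 50 reads.

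Peak density differed between the proteins in 3782 of 15145 genes, 1922 higher in PTBP1 and 1860 higher in IGF2BP2 (limma, adjusted p under 0.05, 2 libraries each). This split depended on the scaling and on the peaks counted, with 2232 and 1454 under TMM scaling and 2009 and 2510 with a pseudocount of 2, 3190 and 3473 by nucleotides covered, and 2763 and 1299 for peaks of at least 10 IP reads, a choice made after seeing the data. The largest differences toward PTBP1 were found in genes nearly free of IGF2BP2 peaks. TEX9 had 29 and 21 PTBP1 peaks and no IGF2BP2 peak (log2 difference 4.96 ± 0.57 SE, limma adjusted p = 0.003), and the polycomb gene PHC1 had 23 and 26 and none (4.95 ± 0.58). The glycine receptor gene GLRA1 had 44 and 37 PTBP1 peaks against 2 and 0 (4.50 ± 0.72), and ADTRP 38 and 37 against 0 and 2 (4.39 ± 0.76). LINC01291 (4.43), the splicing factor gene ZCRB1 (4.30), PLGLB1 (4.29), LOC100133315 (4.23 ± 1.00 SE), BCCIP (4.12) and PAPPA2 (3.99 ± 0.83 SE) completed the 10. Without IGF2BP2 replicate 1 or 2, LOC100133315 was at 2.45 or 6.0 and PAPPA2 at 5.35 or 2.63, and LOC100133315 did not pass without the filter on peaks (limma adjusted p = 0.059). GLRA1, ADTRP, LINC01291 and BCCIP also had peaks in a single IGF2BP2 library, so the size of their differences likewise depends on which library is kept. LINC01291 (1.16, limma adjusted p = 0.364) and LOC100133315 (2.20, limma adjusted p = 0.059) did not pass for the best 25% of peaks, nor PLGLB1 (0.92, limma adjusted p = 0.189) for peaks of at least 10 IP reads. Only GLRA1 among them held regions enriched in both PTBP1 replicates, 2 in introns.

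Differences toward IGF2BP2 were smaller. CPEB2, a regulator of mRNA polyadenylation and translation, had 16 and 14 IGF2BP2 peaks against 4 and 5 of PTBP1 (log2 difference -2.33 ± 0.38 SE, limma adjusted p = 0.007). LAMA5-AS1 had 34 and 34 against 11 and 14 (-2.11 ± 0.25, or -1.13 ± 0.58 and no longer past the threshold without mirrored peaks), ITPRIPL2 51 and 42 against 19 and 17 (-2.03 ± 0.19) and NELFB, a subunit of the negative elongation factor, 59 and 48 against 23 and 21 (-1.95 ± 0.17). NR2C1 (-2.11), KCTD11 (-2.07), ZNF316 (-2.04), MEI1 (-2.03), TESK1 (-2.0) and TONSL (-1.96) completed the 10. KCTD11 also lost its call without mirrored peaks, and NR2C1 lost its call by nucleotides covered. NR2C1 did not pass without PTBP1 replicate 2 (-1.55, limma adjusted p = 0.070), nor did it (-1.20, limma adjusted p = 0.112) or NELFB (-0.13, limma adjusted p = 0.823) for the best 25% of peaks, and TONSL had the opposite direction for peaks of at least 10 IP reads (0.68, limma adjusted p = 0.574). KCTD11 held 6 enriched IGF2BP2 regions in its 3′ UTR and TESK1 3 in coding sequence. The count of genes rests on all peaks: with enriched peaks it was 976 of 2515 genes, and of the 1266 genes called over all peaks that could be tested there, 413 had the opposite direction. Without PTBP1 replicate 1 or 2 the count was 2267 or 2473, and without IGF2BP2 replicate 1 or 2 it was 6388 or 6097.

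The genes with the most reproducible regions were largely the same for both proteins. CDH13, a cadherin gene, led for PTBP1 with 859, followed by the potassium channel gene KCNMA1 with 820, DIP2C with 729, LDLRAD4 with 639, ZMIZ1 with 625, VAV2 with 615, the hedgehog pathway gene GLI2 with 612, SEPTIN9 with 579, MIR4435-2HG with 568 and MAD1L1 with 567. For IGF2BP2 the order was VAV2 with 549, the spindle checkpoint gene MAD1L1 with 548, ZMIZ1 with 472, DIP2C with 468, SEPTIN9 with 463, the collagen gene COL5A1 with 423, GLI2 with 398, KCNMA1 with 387 and TRIO with 373. Most of these regions were not enriched. Of enriched regions, MAD1L1 held 2 of PTBP1 and 59 of IGF2BP2, VAV2 3 and 45, CDH13 16 and 2, and KCNMA1 39 and 23.

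Of the 28 cytoskeleton and adhesion genes tested, 15 had higher density in IGF2BP2, 3 in PTBP1 and 10 did not pass, with 17 and 4 adjusted over the list alone (median log2 difference -0.56). Camera gave an adjusted p of 9.0e-04 with the preset correlation and an adjusted p = 0.566 with an estimated correlation, so this call was lost. ACTN4 (-0.72) and ACTN1 (-0.29), both α-actinins, which crosslink actin, were higher in IGF2BP2. DST (0.08) and MACF1 (0.11) did not pass, and their enriched regions numbered 32 and 37 for PTBP1 against 4 and 1 for IGF2BP2. With enriched peaks in place of all peaks, a choice made after seeing the data, the list had the opposite direction (camera adjusted p = 0.280, 22 members tested). In all, 21 members held an enriched PTBP1 region, 23 an enriched IGF2BP2 region and 18 both.

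Genes known as PTBP1 targets, the family included, were not denser in PTBP1 peaks as a group. Of 21 tested, 4 were higher in PTBP1, 10 in IGF2BP2 and 7 did not pass, with 4 and 12 adjusted over the list alone (camera adjusted p = 0.063). CALD1 (0.65 ± 0.17 SE), an actin-binding protein gene, was among those higher in PTBP1, and BIN1 (-1.35), FGFR1 (-0.84) and PTBP1 itself (-0.67) among those higher in IGF2BP2. ACTN1, whose alternative exons PTBP1 is known to repress, held 9 enriched PTBP1 regions, all in introns, and 4 of IGF2BP2. Of the 22 members in the files, 10 held an enriched PTBP1 region and 14 an enriched IGF2BP2 region.

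Of 22 genes known as IGF2BP targets in the files, 16 held an enriched IGF2BP2 region and 8 an enriched PTBP1 region, and the same 8 held both. In density, 1 of 20 was higher in PTBP1, 3 in IGF2BP2 and 16 did not pass, with the same 1 and 3 adjusted over the list alone (camera adjusted p = 0.672). IGF1R (0.39 ± 0.08 SE) was higher in PTBP1, and IGF2BP1 (-0.56 ± 0.11 SE), with 4 enriched IGF2BP2 regions in its 3′ UTR, was higher in IGF2BP2. CD44 (-0.25) did not pass. The list's median was -0.06 and its mean 0.02, and camera's direction was toward IGF2BP2.

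Splicing regulators held enriched PTBP1 regions in 20 of 29 members and enriched IGF2BP2 regions in 13. In density 1 was higher in PTBP1, the splicing factor gene RBFOX2 (0.94 ± 0.15 SE), 7 in IGF2BP2, among them U2AF2 (-0.69) and CELF1 (-0.74), and 21 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.128). With enriched peaks, a choice made after seeing the data, the 9 members tested lay toward PTBP1 (camera adjusted p = 0.045 with the preset correlation). An estimated correlation was not run for enriched peaks. MBNL2 (0.29) did not pass and held 5 enriched regions of each protein. Of 30 cell cycle genes, 4 were higher in PTBP1, CDK6 (0.43) and RB1 (0.79) among them, 5 in IGF2BP2 and 21 did not pass, with 4 and 5 adjusted over the list alone (camera adjusted p = 0.424). CDK6 and CDKN1A, a CDK inhibitor gene, held 7 enriched IGF2BP2 regions each in their 3′ UTRs and CCND1 9, while PTBP1 had 0 in these 3 UTRs.

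Of 26 extracellular matrix and mesenchymal genes, 3 were higher in PTBP1, COL6A3 (2.38), the fibronectin gene FN1 (1.67) and SPARC (0.49), 7 in IGF2BP2, among them COL5A1 (-0.88) and TIMP2 (-0.54), and 16 did not pass, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.310). Their median difference was -0.22 and their mean 0.01, and camera's direction was toward IGF2BP2. Of 12 glial and neural genes, 2 were higher in PTBP1, NCAM1 (1.31) and VCAN (1.25), 5 in IGF2BP2, among them CSPG4 (-0.91) and TUBB3 (-0.56), and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.481). EGFR (-0.03) did not pass and held 232 reproducible regions of PTBP1 and 106 of IGF2BP2.

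Of 29 cytosolic ribosomal protein genes, none was higher in PTBP1, 5 were higher in IGF2BP2, among them RPS3 (-1.12) and RPS19 (-1.04), and 24 did not pass, with 2 in IGF2BP2 adjusted over the list alone (camera adjusted p = 0.055). These genes have many processed pseudogenes, whose reads were not told apart here. With enriched peaks, a choice made after seeing the data, 5 members were tested and lay toward PTBP1 (camera adjusted p = 0.027 with the preset correlation). The estimated correlation was run over all peaks only, where camera gave an adjusted p of 0.566 for this list, toward IGF2BP2. Of 27 nuclear genes of oxidative phosphorylation, NDUFA9 (3.46) was higher in PTBP1, ATP5F1B (-1.13) in IGF2BP2 and 25 did not pass, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.639). Their median was -0.25 and their mean 0.12, and camera's direction was toward IGF2BP2. Of 10 abundant non-coding RNA genes, RN7SL2 (-0.97), GAS5 (-1.39) and H19 (-1.59) were higher in IGF2BP2 and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.141), with NEAT1 (-0.32) and MALAT1 (0.44) among the latter. Of the markers of blood, epithelium, liver and pancreas, 5 of 12 could be tested and none passed (camera adjusted p = 0.333), none also adjusted over the list alone. KRT8, a keratin gene of simple epithelia, held 55 and 30 reproducible regions.

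A reproducible region of each was found in 12716 genes, against 10916 expected of independent lists among 19767 genes. Genes with regions enriched in both replicates numbered 1224 for both proteins, against 537 expected, or 710 among the 14465 genes with a peak in all 4 libraries. These values are not matched on transcript abundance. Of the 303982 PTBP1 regions, 19.9% (95% Wilson interval 19.7% to 19.996%) overlapped an IGF2BP2 region, against 4.11% ± 0.03 (SD over 100 shuffles) inside the same genes and 5.79% after a move of 500 nt. Of the 6990 enriched PTBP1 regions, 189 (2.70%, 2.35% to 3.11%) overlapped an enriched IGF2BP2 region, against 0.37% ± 0.08 (SD over 100 shuffles).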

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

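The tests of chromosome scaling and of transcript abundance were chosen after their results were seen, as were the common scale, the enriched peaks and the change of the minimum of peaks per region.

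Over all peaks, the median within-gene log2 difference of 3′ UTR minus coding sequence was above 0 in both IGF2BP2 libraries and below 0 in both PTBP1 libraries, and the means of the proteins lay 1.55 apart, a difference that was not tested. At 10 to 20 IP reads the PTBP1 medians were 0 and -0.09 with at least 1 peak per region and 0.12 and -0.10 with at least 3, so a PTBP1 preference for coding sequence within genes was not seen there. Over all peaks, coding sequence minus intron was above 0 in both PTBP1 libraries and below 0 in both IGF2BP2 libraries, with an IGF2BP2 minus PTBP1 difference of -1.21, also not tested. Peaks overlapped by a peak on the other strand made up 11.5% and 11.6% of the PTBP1 lists and 10.7% and 10.8% of the IGF2BP2 lists. By another measure, 16.3% and 15.7% of the PTBP1 peaks in 3′ UTRs and 12.2% of those in each IGF2BP2 library lay on the strand opposite to most exonic peaks of their gene.

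For enrichment of PTBP1 in coding sequence and of IGF2BP2 in 3′ UTRs, transcript abundance acts on all regions of a mature mRNA alike. The smallest within-gene gap between an IGF2BP2 and a PTBP1 library was 1.53, with at most 0.03 between replicates. The difference between the proteins was thus also present within genes. This cannot decide on abundance as a cause. Abundance is that of 1 cell line for both proteins, and the comparison was chosen after its result was seen. Among peaks of 10 to 20 IP reads, with input reads not matched and at least 1 peak per region in place of 3, the smallest gap was 1.00, which did not exceed the bound of 1 set before this test and stayed above the 0.5 set for depth as the cause, and it came from the IGF2BP2 side. With the minimum exchanged it was 1.46 over all peaks and 1.06 at 10 to 20 reads, over other sets of genes. Whether depth accounts for part of the pattern stays open, and the binding of the proteins themselves is untested here.

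For the high scores of chromosomes 14 and 21 in PTBP1, scaling of the reads per chromosome fits: on one scale their enriched share was at most 0.875 times that of the other chromosomes. Heavy input reads of the 7SL RNA genes on chromosome 14 may weigh on its total. Peaks of RN7SL1 and RN7SL2 had a median log2 at least 7 units under that of the chromosome (-7.00 in the PTBP1 library nearer to 0), which this explanation needs. It was not tested for chromosome 21, and no biological explanation was tested.

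PTBP1 peak density was higher in genes of long extent, with a Spearman correlation of 0.252 across 14664 genes, which are not independent replicates. In the longest 20% of genes 996 were higher in PTBP1 and 165 in IGF2BP2, against 107 and 382 in the shortest 20%. A larger share of peaks in introns is argued against as the cause, since intronic peaks alone gave 0.265. After PTBP1 reads were thinned toward the IGF2BP2 median the correlation was 0.121, between the bounds of 0.1 and 0.2 set before. The thinning was incomplete, since all peaks without recovered reads were kept. The thinned PTBP1 lists held 443218 and 408610 peaks, against 362700 and 341305 of IGF2BP2. Depth could thus account for part or all of the correlation and cannot be told apart from the proteins here.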

How the results depend on the processing

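Alternatives with enriched peaks, at least 10 IP reads, peaks over 4 nt, mirrored or abutting peaks, chromosomes 14 and 21 or single exonic regions were chosen after seeing the data. Where no cause is given, the cause was not tested.

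Peak reproducibility stayed above its shuffled level in all alternatives run. In the order PTBP1 replicates 1 and 2, IGF2BP2 replicates 1 and 2, it was 38.8%, 43.3%, 37.7% and 40.03% with reciprocal overlap of 50%, 57.9%, 62.9%, 39.1% and 41.7% for the best 25% of peaks, and 45.8%, 51.4%, 31.1% and 32.3% for enriched peaks.

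Region share differences for coding sequence and 3′ UTR kept their direction in all alternatives run. For intron, coding sequence and 3′ UTR they were -1.25, 6.81 and -4.96 points for reproducible peaks, -8.41, 17.1 and -8.40 for the best 25%, 1.15, 3.83 and -4.73 by nucleotides, -8.44, 21.3 and -12.7 for enriched peaks, 2.36, 10.4 and -11.1 at 10 or more IP reads, -1.22, 4.38 and -3.22 without mirrored peaks, and 0.13, 3.72 and -3.80 for peaks over 4 nt. The intron difference reversed by nucleotides, at 10 or more reads and over 4 nt.

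The 3782 genes with different density became 6663 by nucleotides, 5932 with abutting peaks counted once and 2267 to 6388 leaving out a replicate, where the lone library is assumed to vary like the other group. Fewer genes could be tested with exonic peaks (1499 calls), coding-sequence peaks (1116), 3′ UTR peaks (311) and enriched peaks (976). With a replicate block, which pairs libraries by number alone, 4763 passed; replicate differences of both proteins did not go together (r = -0.002 across 15145 genes). Of the genes called over all peaks and tested again, the direction was opposite for 877 of 2792 with the best 25%, 542 of 2795 with exonic peaks and 545 of 2852 at 10 or more reads. The direction of a density call thus depends on which peaks are counted. For the best 25%, the unequal scale of chromosomes was not separated from the strength of peaks. Of 20 named genes, 1 reversed: TONSL, at 10 or more reads (0.68, limma adjusted p = 0.574). Calls were lost for 4 of 13 tested with the best 25% (LINC01291, LOC100133315, NR2C1 and NELFB), 3 of 10 with coding-sequence peaks, 2 of 10 with exonic peaks, 2 of 19 without mirrored peaks (LAMA5-AS1 and KCTD11), 1 of 3 with 3′ UTR peaks, 1 of 13 at 10 or more reads, and 1 of 20 each with no filter, by nucleotides and without PTBP1 replicate 2 (NR2C1 in the last 2).

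Shared target genes numbered 5112 for the best 25%, 1224 for enriched regions and 1577 for regions enriched as deposited. With any peak in either replicate the count decides nothing, since both lists together make up the background. Position overlap was 11.3% with reciprocal overlap of 50%, 2.70% for enriched regions and 13.6% to 29.5% leaving out a replicate.

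Of 11 lists, 1 passed with the preset correlation and 0 with the estimated correlation. With enriched peaks 2 of the 9 lists that could be tested passed with the preset correlation, and the estimated correlation was not run there. With enriched peaks 8 lists turned toward PTBP1, at camera adjusted p of 0.548 for cell cycle, 0.280 for cytoskeleton and adhesion, 0.027 for cytosolic ribosome, 0.061 for extracellular matrix, 0.866 for IGF2BP targets, 0.548 for non-coding RNAs, 0.885 for PTBP1 targets and 0.045 for splicing regulators.

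Motif enrichments, intronic distances, positions in 3′ UTRs, regions from a reference annotation and shuffles within a region class were not run, since no genome sequence or exon annotation was used. The median was 4 recovered IP reads per IGF2BP2 peak, and peaks of few reads were found again less often in every library. At 3 reads the share was 27.1% and 31% for IGF2BP2 and 12.3% and 19.3% for PTBP1. An effect of weak peaks on the counts of peaks per gene was not tested.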

Other observations

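The gene list tested here was written after acidic-protein genes were seen among the strongest PTBP1 regions, and intron genes were chosen after their values were seen.

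AHNAK, which encodes a giant scaffold protein, held the most enriched PTBP1 regions annotated as intron, 57 of 4059, between 62519078 and 62540928 of chromosome 11, and 27 of IGF2BP2. The intron label is that of the submitters. It was not checked against exons, so whether these regions lie outside coding sequence is not known. PTBP1 also had 32 in NBDY and 23 in COPG2, a coatomer subunit gene, where IGF2BP2 had 0 and 2. IGF2BP2 had 41 in RXRA, a retinoid receptor gene, where PTBP1 had 0, and 33 in the chromatin regulator gene ANKRD11, where PTBP1 had 6. It had 29 in ZBTB46, all within 63815172 to 63816199 of chromosome 20, where PTBP1 had 0. The ZBTB46 regions that led by the deposited score overlapped IGF2BP2 regions on the other strand. Whether these are reads of an intron was not checked.

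A hypothesis is that PTBP1 regions in coding sequence gather in genes for proteins with long acidic stretches. HSP90B1, HSP90AA1, HSP90AB1, ANP32B, HMGB1 and NCL gave the idea and were left out of the list. The leading HMGB1 regions were annotated to its 3′ UTR. ANP32A, HMGB2 and HMGB3 in the list are of the same gene families as ANP32B and HMGB1, so the list is not fully independent of the idea. Of 19 other such genes, 12 held an enriched PTBP1 region in coding sequence (ANP32A, HMGB2, HMGB3, SET, NAP1L1, NAP1L4, CANX, UBTF, SSRP1, CENPB, NASP and RSF1), against a mean of 2.48 in 10000 random lists matched on coding-sequence peaks, of which fewer than 1 in 20 reached over 6. In the same genes IGF2BP2 had 0 in coding sequence (mean 0.803) and 5 in 3′ UTRs (mean 2.83). The random lists were not matched on transcript abundance or on reads per peak, so these may lie behind the difference. The sequence of these regions was not examined, so codon use or base composition may also lie behind the count of 12 for genes for proteins with long acidic stretches.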
